A study of Homo sapiens with 6 samples.

How the data were processed

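Messenger RNA was measured by stranded RNA sequencing in 6 libraries of HuT78, a human cutaneous T cell lymphoma line. The deposited table holds raw read counts per gene, with 1 column per library and no pooling, and 33121 genes were listed, of which 11229 had no count in any library. The authors' processing notes name cutadapt, STAR, featureCounts and DESeq2, without versions, and the build hg38. The annotation, the strand setting and the step that made the table are not given in the sources used here. The identifier column is headed as Ensembl identifiers but holds gene symbols, which were used as given. Whole numbers with different totals per library were found in each column, as raw counts require.

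Libraries were grouped by the labels into parental untreated, parental with vorinostat and resistant cells, with 2 libraries each. The treatment label of the libraries called untreated here reads Control, which does not tell no treatment from a vehicle. Total counts ranged from 52480731 to 63842144 per library, and counts are reads without molecular identifiers. Counts were fitted with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1. Genes passing filterByExpr were tested, 16078 in all, and these held 99.98% of all counts. TMM factors were 0.947 and 0.928 for untreated, 1.15 and 1.2 for vorinostat and 0.904 and 0.914 for resistant libraries. One model with a mean per group was fitted to all 6 libraries, and each pair of groups was compared by the two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 for the adjusted p. The common biological coefficient of variation was 11.2%. Levels are given as CPM (library-size-scaled counts in the usual unit of edgeR) on TMM-scaled library sizes with the SD of the 2 libraries, and fold changes as fitted by edgeR with their SE.

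Fixed gene lists, 45 in all, covered drug response, cell cycle, apoptosis, T cell identity, signalling, metabolism, stress, markers of other cell types and RNA quality. In each comparison 44 were tested, since no member of the list of mitochondrially encoded genes was among the genes tested. Counts of list members cover only members tested. A member almost silent in untreated cells passed the filter only through reads in other libraries, so counts in lists of such genes lean towards increases. Each list was tested against the other genes by camera with a preset correlation of 0.01, and the tests were repeated with an estimated correlation and by fry, whose directional test asks only whether the members move 1 way on balance. With an estimated correlation, camera takes its degrees of freedom from the residuals of the fit, which are few with 6 libraries in 3 groups. A call lost in that setting therefore need not mean that members were correlated. The adjusted p of a list is Benjamini-Hochberg adjusted over the 44 lists of 1 comparison.

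Named genes followed a rule. They were the 8 genes with the largest increase and the 8 with the largest decrease in each comparison, among genes past the threshold with a mean log2 CPM of at least 4 and no overlap between the groups, leaving out Y-linked genes and XIST. To these were added up to 4 members with the smallest p of each list described, in each direction where it moved both ways, and always HDAC1 to HDAC11, CDKN1A, MYC, BCL2, BCL2L11, ABCB1 and NFKB2. A few genes that the rule selects are not reported here, and were left out without replacement. Genes named outside this rule are identified where they occur. The groups, comparisons, model, thresholds, gene lists, naming rule and alternative settings were chosen before the data were examined, except where stated.

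The tests were checked on simulated data. With changes of 1 on the log2 scale planted in 100 genes, 87, 91 and 85 were recovered in vorinostat against untreated, resistant against untreated and resistant against vorinostat cells, with 13, 19 and 10 false calls. With planted changes of 2, 99 were recovered in each comparison. Both sizes were planted only in genes at 1 CPM or more in untreated cells. A list of 30 genes shifted by 0.5 was found by camera, and 0 of 44 other lists were called. Genes were drawn independently there and only the planted list was changed, so this does not check camera where genes are correlated. Both comparisons with untreated cells use the same 2 control libraries, so the overlap of their calls was also counted in 100 simulations of unchanged groups with shared controls. After the data were seen, 40 simulations of unrelated changes were added: changes of the sizes called were planted in each group, those of the resistant line on other genes drawn within 20 bins of untreated level. The same bins gave the number of members of each list expected to be called if they were called as often as all genes of their level, with an exact two-sided p from all draws of as many genes from each bin, Benjamini-Hochberg adjusted over the lists of 1 comparison and direction. This test takes genes as independent. The effects planted were those fitted, and these simulations gave fewer calls than the data.

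Runs of neighbouring genes were examined in the 10216 autosomal genes with a mean log2 CPM of at least 2 that could be placed on GRCh38. The median log2 fold change was taken in windows of 41 genes, the threshold came from 1000 permutations of gene order, and overlapping windows past it were merged. A lowess trend on GC content was then removed, for the 99.4% of these genes with a GC value. A planted shift of -0.6 over 345 genes was found in 100% of the windows inside it and in 0 of 9031 windows outside. The windows, regions and GC step were designed after an exploratory scan of the data had shown regional shifts.

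Alternatives were RLE, upper-quartile and library-size-only scaling, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, a fit of only the 2 groups compared, a block by the run of library codes, an adjusted p under 0.01, edgeR's glmTreat against a log2 fold change of 0.5, and leaving out each library in turn. Removal of mitochondrial rRNA and tRNA genes before library sizes were taken was added after the data were seen, as was a split of the untreated libraries, in which each comparison used 1 of them and overlaps were counted both ways. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used for regions and figures. With 2 libraries per group, regrouping of libraries and outlier tests within groups were not possible. The list of mitochondrially encoded genes and inference of sex from expression were left out.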

Results

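Gene expression was measured in HuT78, a human cutaneous T cell lymphoma line, in 3 groups of 2 libraries. Parental cells were untreated or received 2 µM vorinostat, an inhibitor of histone deacetylases, for 48 h. The vorinostat-resistant line HuT78VR was raised by dose escalation and grown under 5 µM vorinostat, and the labels do not say whether drug was present in the 48 h before lysis. Total counts were 61610363 and 57688877 for untreated, 53319582 and 52480731 for vorinostat and 53611838 and 63842144 for resistant libraries. Across genes, log2 CPM correlated within groups with Pearson's r of 0.990 to 0.995, genes not being independent replicates, and the first principal component (67.1% of the variance) set the vorinostat libraries apart from the other 4. No label says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Mitochondrial rRNA and tRNA genes took 0.443% and 0.631% of counts in the vorinostat libraries, 0.29% and 0.108% in the untreated and 0.287% and 0.16% in the resistant ones.

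Vorinostat against untreated parental cells gave the acute response to the drug. CDKN1A, which encodes the cell cycle inhibitor p21 (chromosome 6, 36676463 to 36687332), rose 42.0-fold, from 1.467 ± 0.0131 to 61.75 ± 5.91 CPM (SD, n = 2; log2 fold change 5.39, SE 0.148, adjusted p = 2.09e-08). PEG10, an imprinted gene of retrotransposon origin, rose 81.7-fold, and DHRS2, a short-chain dehydrogenase, rose 44.6-fold to 142.1 ± 20.8 CPM. LGALS1 (galectin-1), FN1 (fibronectin), the long noncoding RNA MIAT, GSN (gelsolin) and the histone demethylase gene KDM5B rose 25- to 32.3-fold. The largest decreases were in LTB (lymphotoxin beta), which fell 19.8-fold from 231.3 ± 37.4 to 11.71 ± 0.0255 CPM, and in PVRIG, CMAHP, AGMAT, MBNL3, KCNQ5, SLA2 and the chemokine receptor gene CCR8, which were 10.5- to 18.4-fold lower.

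Genes for making ribosomes and for DNA replication fell with vorinostat. Among tested genes at 100 CPM or more in untreated cells 68.9% fell and 8.31% rose, and among those under 1 CPM 59.8% rose. Levels taken over all 6 libraries gave 64.7% and 11% at 100 CPM or more, and 51.1% rose under 1 CPM. Binning by the untreated libraries reuses the values that the fold changes rest on. Genes almost silent there passed the filter only through reads in other libraries, so part of the increase at low levels is set by the choice of genes. Each list was therefore also set against all tested genes of the same level in untreated cells, in an exact two-sided test added after the data were seen. That test takes genes as independent. Of 31 ribosome biogenesis and MYC-regulated genes, 30 fell and 0 rose, and 30 fell adjusted over the list alone (camera adjusted p = 8.5e-09, and adjusted p = 0.4 with an estimated correlation). Among them were UBTF, a transcription factor of RNA polymerase I (log2 -1.55), WDR43 (-1.26), NOP16 (-1.57) and LDHA (-1.46). Of 38 DNA replication and G1/S genes, 35 fell and 1 rose, with equal counts adjusted over the list alone (adjusted p = 2.2e-07, and adjusted p = 0.61 with an estimated correlation). TYMS fell by 1.77, CDC25A by 1.71 and GINS3 by 1.56, and TK1 rose by 1.75. Of 34 mitosis genes, 20 fell, with CCNA2 (-1.14) and MAD2L1 (-1.09), and 1 rose (19 and 1 adjusted over the list alone; adjusted p = 0.005, and adjusted p = 0.65 with an estimated correlation), but upper-quartile scaling gave 13 lower and 8 higher. Of 30 double-strand break repair genes, 21 fell, with NBN (-1.53) and XRCC6 (-1.11), and 2 rose, both counts standing adjusted over the list alone (adjusted p = 0.0018, and adjusted p = 0.59 with an estimated correlation), and library size alone gave 14 and 8. Of 35 nuclear-encoded oxidative phosphorylation genes, 26 fell, with NDUFS3 (-1.39) and UQCRFS1 (-1.21), and 2 rose, also adjusted over the list alone (adjusted p = 0.00026, and adjusted p = 0.61 with an estimated correlation), and library size alone gave 16 and 6. At the rates of genes of the same level, 20.8 of the ribosome and 23.5 of the replication genes would have fallen (exact adjusted p = 0.00096 for each). For mitosis genes that number was 21.6 (exact adjusted p = 0.95), for repair genes 16.9 (0.44) and for oxidative phosphorylation genes 20.3 (0.25). For these 3 lists a difference from their level was not shown.

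T cell receptor genes fell with vorinostat, while neuronal and fibroblast markers rose. The lists of B cell, epithelial, myeloid and erythroid markers did not pass the camera threshold. Yet 8 of 10 myeloid markers rose and 2 fell, and 4 of 6 erythroid markers rose and 1 fell. Of 11 B cell and 11 epithelial markers, 5 of each rose and 4 of each fell. Of 35 T cell receptor and proximal signalling genes, 24 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 6.9e-05, and adjusted p = 0.59 with an estimated correlation), and library size alone gave 21 and 6. CD247, the zeta chain of the receptor, fell by 1.89, UBASH3A by 2.37, CD3D by 1.69 and CD6 by 1.70, and the costimulatory receptor gene CD28 rose by 3.69. Of 24 neuronal markers, 18 rose, with SYP (4.11) and TUBB3 (4.02), and 2 fell, also adjusted over the list alone (adjusted p = 0.00083, and adjusted p = 0.5 with an estimated correlation). Of 12 fibroblast markers, 9 rose, with FN1 (4.95), SPARC (3.68) and COL1A1 (2.07), and 1 fell, also adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.5 with an estimated correlation). At the rates of genes of the same level, 17.3 of the T cell receptor genes would have fallen (exact adjusted p = 0.095), and 12.1 of the neuronal (0.075) and 4.7 of the fibroblast markers (0.038) would have risen. For the T cell receptor and neuronal lists a difference from their level was not shown. Only 24 of 34 neuronal, 12 of 16 fibroblast, 10 of 17 myeloid and 6 of 17 erythroid markers were tested. Markers almost silent in untreated cells passed the filter only through reads in other libraries, so the share that rose is partly set by the filter. The genes of the same level passed that filter too. Of 4079 tested genes at a low level, under 1 CPM in untreated cells, 1260 were higher and reached 1 CPM with vorinostat. With counts of all genes thinned to the total of the smallest library, 17027 and 17335 genes had at least 5 counts, against 15255 and 15066 in untreated libraries.

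Of 16 measured genes widely reported to rise with inhibitors of histone deacetylases, 13 rose and 1 fell with vorinostat (14 and 1 adjusted over the list alone; camera adjusted p = 0.00028, and adjusted p = 0.59 with an estimated correlation), with CLU at 4.84 on the log2 scale. As fixed, this list shares TUBB3, STMN3 and SYNGR3 with the neuronal markers. Of 27 MAPK feedback genes, 18 rose, with FOS (4.53), DUSP5 (2.05) and ETV5 (2.31), and 1 fell, also adjusted over the list alone (adjusted p = 0.0018, and adjusted p = 0.5 with an estimated correlation). FOS, FOSB, JUN, JUNB, EGR1, IER2, IER3 and DUSP1 also belong to 18 immediate-early genes that can mark handling. Apart from FOS they are named here for membership only. Of those 18 genes 12 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0022, and adjusted p = 0.5 with an estimated correlation). The results for MAPK feedback and immediate-early genes are therefore not separate. Of 16 drug efflux transporters, 11 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.59 with an estimated correlation): ABCB1, which encodes P-glycoprotein, rose 26.9-fold from 0.5897 ± 0.0148 to 15.9 ± 1.26 CPM, ABCA7 rose by 3.02 and ABCA2 by 2.65 on the log2 scale, and ABCC1 fell by 1.05. Of 15 acetyltransferases and bromodomain readers, 11 fell, with KAT7 (-1.21) and CREBBP (-1.17), and 1 rose, KAT2B (0.78), or 13 and 1 adjusted over the list alone (adjusted p = 0.0049, and adjusted p = 0.59 with an estimated correlation), and upper-quartile scaling gave 7 and 1. Of 15 housekeeping reference genes, 10 fell, with PPIA (-1.18), and 1 rose, B2M (0.35), also adjusted over the list alone (adjusted p = 0.0049, and adjusted p = 0.59 with an estimated correlation), and without untreated library 2 B2M stood at 0.25 (adjusted p = 0.0538). Library size alone gave 6 lower housekeeping genes and 1 higher, and at the rates of their level 10.6 of these genes (exact adjusted p = 1) and 8.8 of the acetyltransferases and readers (0.65) would have fallen. At such rates 6.7 of the genes widely reported to rise (exact adjusted p = 0.03), 10.3 of the MAPK feedback genes (0.037), 6.2 of the immediate-early genes (0.038) and 6.7 of the transporters (0.11) would have risen. For the transporters, the housekeeping genes and the acetyltransferases and readers a difference from their level was not shown.

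In the edgeR quasi-likelihood test 5528 genes were higher and 5068 lower with vorinostat, 65.9% of those tested, and 2204 rose and 217 fell by 2 or more on the log2 scale. The split depended on scaling: upper-quartile factors gave 6990 higher and 3579 lower, with the median of all genes 0.24 higher, and library size alone gave 7634 and 3113, with the median 0.32 higher. RNA content per cell was not measured, so changes are relative to the TMM scale.

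**Figure D1:**
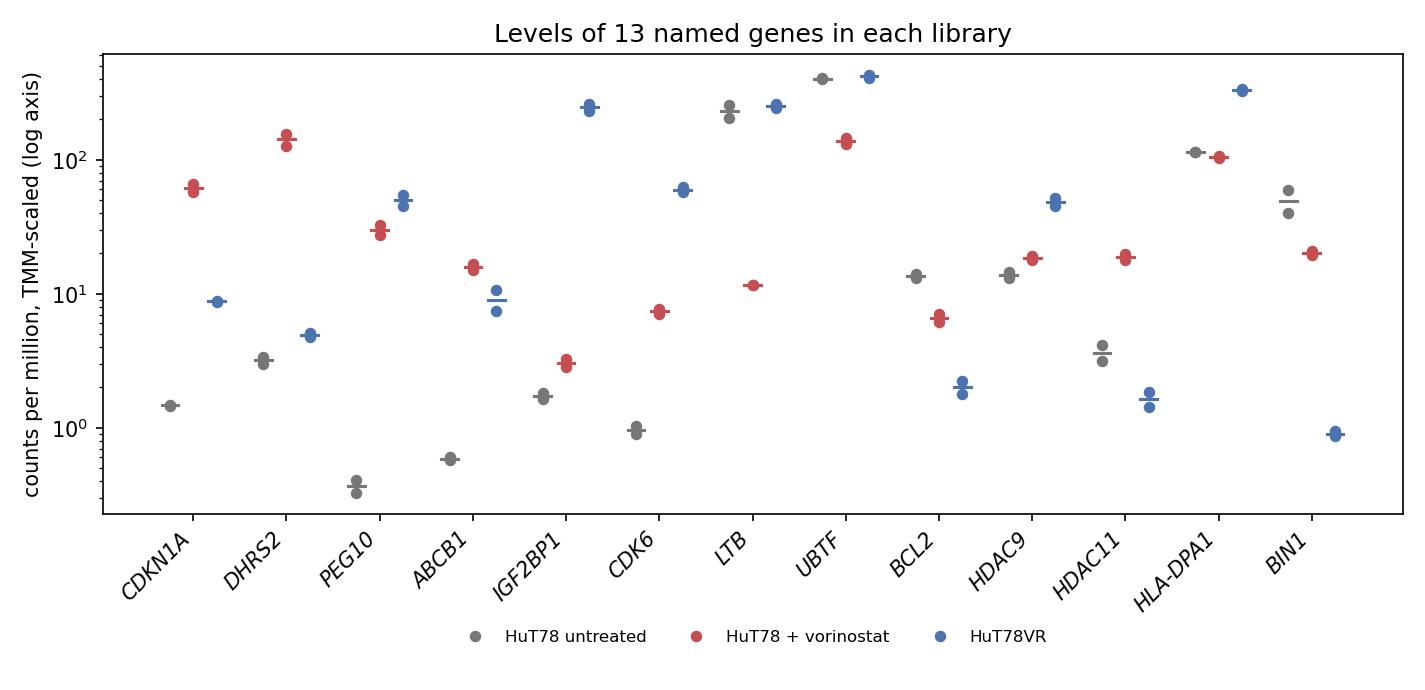
CPM on a log axis of 13 named genes in each of the 6 libraries, with points for libraries and lines for group means. CDKN1A was at 1.467 CPM in untreated, 61.75 in vorinostat and 8.792 in resistant cells, and IGF2BP1 was at 246.1 CPM in resistant cells.

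Resistant against untreated parental cells compared the lines, and an effect of any drug present in the resistant wells would be part of that difference. IGF2BP1, an mRNA-binding protein gene (chromosome 17, 48996558 to 49056145), was 142.0-fold higher, at 246.1 ± 22 against 1.73 ± 0.143 CPM (SD, n = 2; log2 7.15, SE 0.139, adjusted p = 1.17e-09). PEG10 was 136.0-fold higher, and CDK6, a kinase that drives entry into S phase, was 61.8-fold higher at 59.76 ± 3.57 CPM. KDM5B, the cortactin gene CTTN, EEF1A2 and NAV2 were 20- to 26.9-fold higher, CTTN lying in a region of chromosome 11 whose genes were higher as a set. BIN1, a membrane-curving adaptor, was 54.5-fold lower at 0.9044 ± 0.0535 CPM, and EVPL, APBA2, FAM169A, FHDC1, BAHCC1, the splicing regulator ESRP1 and FLNC were 7.57- to 18.6-fold lower, APBA2 lying on chromosome 15, whose genes were lower as a set. BCL2, which blocks apoptosis, was 6.76-fold lower, at 2.005 ± 0.316 against 13.52 ± 0.735 CPM.

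MHC class II and heat shock genes were higher in the resistant line. Of 17 MHC class II genes, 13 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.00012, and adjusted p = 0.47 with an estimated correlation). HLA-DPA1 was 1.53, HLA-DQB1 2.18 and HLA-DOA 2.40 higher on the log2 scale, while IFI30 fell by 0.87. Of those 13, 10 lay in shifted regions, chiefly that of chromosome 6, 31.7 to 33.2 Mb. Members inside shifted regions had a median of 1.2, against 0.48 for members outside. The chromosome 6 region holds 42 genes, list members among them, and all regions were called from these same fold changes. A larger median inside, here and in the lists below, therefore shows no regional cause. Of 20 heat shock genes, 12 were higher, with DNAJA1 (0.56), HSPB1 (2.24) and HSPA1A (1.29), and 0 lower (13 and 0 adjusted over the list alone; adjusted p = 0.00094, and adjusted p = 0.48 with an estimated correlation). Of the 10 higher heat shock genes that were placed, 4 lay in shifted regions, where the list's median was 0.73 against 0.39 outside. Of 30 NF-kB components and targets, 15 were higher, with ICAM1 (1.59) and CFLAR (1.22), and 3 lower, with BCL2A1 (-2.69), or 17 and 3 adjusted over the list alone (adjusted p = 0.04, and adjusted p = 0.51 with an estimated correlation). Of these 15 higher genes, 3 lay in shifted regions, where the list's median was 0.42 against 0.34 outside.

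Interferon-stimulated and endoplasmic reticulum stress genes were lower in the resistant line. Of 40 interferon-stimulated genes, 21 were lower, with TRIM22 (-2.05), PARP9 (-1.05) and GBP1 (-0.96), and 2 higher, IFI44L (5.75) and BST2 (0.44), also adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.48 with an estimated correlation). Of the 20 lower interferon-stimulated genes that were placed, 8 lay in shifted regions, where the list's median was -0.73 against -0.33 outside. Of 25 endoplasmic reticulum stress genes, 15 were lower, with ATF3 (-2.09), TRIB3 (-1.31) and CREB3L2 (-0.65), and 0 higher (17 and 0 adjusted over the list alone; adjusted p = 0.00028, and adjusted p = 0.48 with an estimated correlation). Of these 15 lower genes, 2 lay in shifted regions, where the list's median was -0.45 against -0.54 outside. Of 30 double-strand break repair genes, 13 were lower, with BLM (-1.07), CHEK1 (-1.13) and BRCA1 (-0.91), and 1 higher, FANCA (0.44), or 15 and 2 adjusted over the list alone (adjusted p = 0.01, and adjusted p = 0.53 with an estimated correlation). Without resistant library 2 FANCA stood at 0.40 (adjusted p = 0.0648). Of these 13 lower genes, 8 lay in shifted regions, where the list's median was -0.68 against -0.18 outside. At the rates of their level 8.2 would have been lower (exact adjusted p = 0.3). The other lists named as higher or lower in the resistant line passed that test, at 0.017 or less.

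Other lists were higher in the resistant line and also with vorinostat. Of 16 genes widely reported to rise with inhibitors of histone deacetylases, 11 were higher, with CDKN1A 5.99-fold, and 1 lower, GLRX (-1.18), or 12 and 1 adjusted over the list alone (camera adjusted p = 0.00094, and adjusted p = 0.48 with an estimated correlation). Of 16 drug efflux transporters, 9 were higher, with ABCB1 15.2-fold and ABCA3 by 3.23 on the log2 scale, and 2 lower (10 and 2 adjusted over the list alone; adjusted p = 0.0017, and adjusted p = 0.48 with an estimated correlation). Of 27 MAPK feedback genes, 15 were higher, with SPRY4 (4.73) and ETV4 (2.23), and 2 lower, with FOSL2 (-1.68), or 17 and 2 adjusted over the list alone (adjusted p = 0.00031, and adjusted p = 0.47 with an estimated correlation). Of 24 neuronal markers, 14 were higher, with SNAP25 (6.07) and NRCAM (3.93), and 2 lower, also adjusted over the list alone (adjusted p = 0.0023, and adjusted p = 0.47 with an estimated correlation). Inside against outside shifted regions, medians were 1.67 and 0.56 for MAPK feedback genes (4 inside) and 0.54 and 0.52 for transporters (6 inside). They were 0.86 and 1.22 for neuronal markers and -0.25 and 1.49 for genes widely reported to rise, each with 1 inside.

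Whole chromosome regions were shifted in the resistant line, a feature chosen after its values were seen. The 345 genes used of chromosome 15 had a median log2 fold change of -0.62 against untreated cells, and each of the 4 pairs of a resistant and an untreated library gave -0.61 to -0.63 against the other autosomes, while pairs with vorinostat libraries gave -0.01 to 0.02. On chromosome 11 the median was 0.45 over 256 genes from 57.7 to 86.3 Mb and -0.67 over 100 genes from 111.9 to 134.3 Mb. Of 9336 windows of 41 genes, 507 were higher and 822 lower past the permutation threshold of 0.365, against 0 and 0 with vorinostat, where the threshold was 0.622. After a trend on GC content was removed, 197 windows were higher and 983 lower past a threshold of 0.334, and 25 merged regions became 14.

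In the edgeR test 3061 genes were higher and 3176 lower in resistant than in untreated cells, 38.8% of those tested. Without resistant library 1 the counts were 1959 and 2035.

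**Figure D2:**
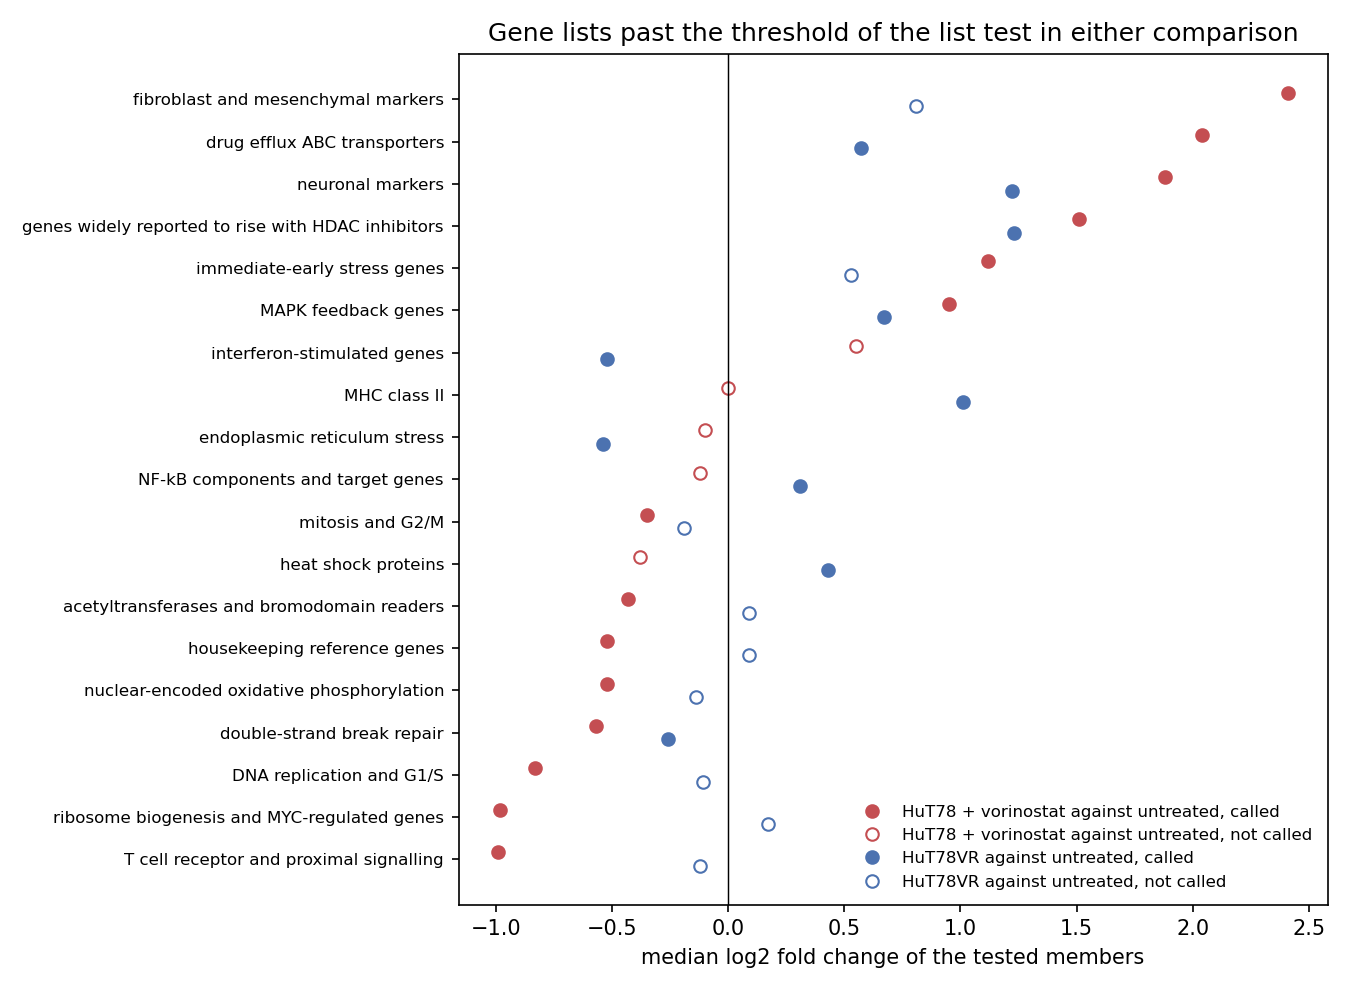
Median log2 fold change of the members of 19 gene lists in vorinostat and resistant cells against untreated cells, with filled symbols for lists past the camera threshold of 0.05 and open ones for the rest. The medians of ribosome biogenesis genes were -0.98 with vorinostat and 0.17 in the resistant line, and those of MHC class II genes were 0.0 and 1.01.

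Resistant cells were compared with vorinostat-treated parental cells to set the lines side by side under the drug, as far as the labels allow. Parental cells had 2 µM for 48 h, and the resistant line was grown under 5 µM. Line, dose and length of exposure therefore cannot be told apart. IGF2BP1 was 80.5-fold higher, LTB 21.5-fold higher at 251.6 ± 10.6 CPM, and SAMD10, FBXO27, CTTN, XCL1, PVRIG and KRT7 were 13.7- to 26.4-fold higher. FN1 was 34.6-fold lower, DHRS2 28.8-fold lower, CDKN1A 7.02-fold lower and HDAC11 11.5-fold lower, and TPMT, SERPINB9, NEAT1, BIN1, LOC101060038 and APBA2 were 11.5- to 24.2-fold lower. Of 31 ribosome biogenesis genes, 31 were higher, with NOP16 (2.06), CAD (1.89) and NPM1 (1.58), also adjusted over the list alone (camera adjusted p = 9.7e-10, and adjusted p = 0.34 with an estimated correlation). Of 38 DNA replication genes, 31 were higher, with TYMS (2.26), and 1 lower (31 and 2 adjusted over the list alone; adjusted p = 1.3e-05, and adjusted p = 0.76 with an estimated correlation), and library size alone gave 23 and 5.

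Heat shock, T cell receptor and MHC class II genes were also higher in resistant than in vorinostat-treated cells. Of 20 heat shock genes, 16 were higher, with DNAJA1 (1.89) and HSPD1 (2.07), and 0 lower, also adjusted over the list alone (camera adjusted p = 0.00061). Of 35 T cell receptor genes, 20 were higher, with CD6 (1.92) and UBASH3A (2.35), and 6 lower, with THEMIS (-5.24), or 20 and 7 adjusted over the list alone (adjusted p = 0.013), and library size alone gave 18 and 11. Of 17 MHC class II genes, 11 were higher, with HLA-DRA (1.94), and 2 lower (11 and 3 adjusted over the list alone; adjusted p = 0.023), and library size alone gave 10 and 5. Of 15 acetyltransferases and bromodomain readers, 12 were higher, with CREBBP (1.65), and 1 lower, also adjusted over the list alone (adjusted p = 0.012), and library size alone gave 9 and 3. Of 35 oxidative phosphorylation genes, 21 were higher, with UQCRFS1 (1.21), and 3 lower, also adjusted over the list alone (adjusted p = 0.0052), and library size alone gave 12 and 11. Of 15 housekeeping genes, 13 were higher, with PPIA (1.60), and 2 lower, also adjusted over the list alone (adjusted p = 0.022), and library size alone gave 6 and 2. At the rates of genes of the same untreated level, 18.7 of the oxidative phosphorylation (exact adjusted p = 1), 16.3 of the T cell receptor (0.59), 10 of the housekeeping (0.4), 8.1 of the acetyltransferase and reader (0.21) and 6.8 of the MHC class II genes (0.19) would have been higher. For these 5 lists a difference from their level was not shown. The numbers were 19.4 for ribosome (1.8e-05), 21.8 for replication (0.015) and 9.9 for heat shock genes (0.025). Of 40 interferon-stimulated genes, 25 were lower, with GBP2 (-3.47), and 7 higher (26 and 7 adjusted over the list alone; adjusted p = 0.0077), where 14.3 would have been lower at the rates of their level (exact adjusted p = 0.0079). Each of these 7 lists had adjusted p = 0.76 with an estimated correlation. In the edgeR test 5122 genes were higher and 5960 lower in resistant than in vorinostat-treated cells, and library size alone gave 3096 and 8156, with the median of all genes shifted by -0.37 on the log2 scale.

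Histone deacetylase genes changed in both comparisons with untreated cells, HDAC5, HDAC6, HDAC9 and HDAC10 being higher in each. With vorinostat 5 of 11 rose, HDAC11 5.16-fold, HDAC5 3.88-fold, HDAC10 2.1-fold, HDAC6 1.94-fold and HDAC9 1.35-fold, and 2 fell, HDAC7 2.1-fold and HDAC1 1.28-fold, also adjusted over the list alone (camera adjusted p = 0.58). In the resistant line 6 were higher, HDAC9 3.5-fold, HDAC6 1.57-fold, HDAC4 1.5-fold, HDAC5 1.47-fold, HDAC10 1.45-fold and HDAC2 1.37-fold, and HDAC11 was 2.22-fold lower, also adjusted over the list alone (adjusted p = 0.2). HDAC3 and HDAC8 passed the test in neither comparison, with log2 fold changes of 0.04 and -0.18 with vorinostat and -0.19 and -0.22 in the resistant line, but with vorinostat HDAC3 gained a call under upper-quartile scaling (0.28) and library size alone (0.36), and HDAC8 without untreated library 2 (-0.28). Upper-quartile scaling and library size alone ended the call of HDAC1 with vorinostat (-0.12 and -0.04). Library size alone gave HDAC1 a call in the resistant line (-0.26) and HDAC2 a call with vorinostat (0.28, against -0.04 under TMM). Leaving out vorinostat library 2 ended the vorinostat calls of HDAC1 (-0.29) and HDAC9 (0.37). In the resistant line the calls ended for HDAC4 without resistant library 2 (0.50), for HDAC10 without resistant library 1 (0.52), and for HDAC5 on leaving out any library except untreated library 2 (0.31 to 0.58) and in a fit of the 2 groups alone (0.56). HDAC7, at 0.26, gained a call without untreated library 2 (0.45) and with a block by the run of library codes (0.27).

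MYC, at 1208.0 ± 210.0 CPM in untreated cells, fell by 0.29 on the log2 scale with vorinostat (adjusted p = 0.0461), a call that ended on leaving out any library except untreated library 1 (-0.12 to -0.33), under upper-quartile scaling (-0.04), a stricter filter (-0.16) and a fit of the 2 groups alone (-0.29), and library size alone gave 0.04. In the resistant line MYC stood at 0.25 (adjusted p = 0.113), or 0.45 without untreated library 2 (adjusted p = 0.000982). BCL2L11, which encodes the apoptosis initiator BIM, stood at 0.21 with vorinostat (adjusted p = 0.0539), where 5 alternatives gave it a call (0.21 to 0.53), and at -0.16 in the resistant line (adjusted p = 0.172). BCL2 was 2.05-fold lower with vorinostat. NFKB2 fell by 0.63 with vorinostat and was 0.42 higher in the resistant line.

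Most genes that responded to vorinostat differed in resistant from treated cells, in the direction of the untreated level. Of the 5528 genes that rose with vorinostat, 1524 (27.6%) were also higher in the resistant line, 723 were lower, and 4271 (77.3%) were lower there than in vorinostat-treated cells. Of the 5068 that fell, 1394 (27.5%) were also lower in the resistant line, 749 were higher, and 3849 (75.9%) were higher than in treated cells. Seen from the resistant line, 49.8% of its 3061 higher genes also rose and 43.9% of its 3176 lower genes also fell with vorinostat. Among the 2204 genes that rose by 2 or more on the log2 scale, the median was 3.33 with vorinostat and 0.83 in the resistant line, and among the 217 that fell as much it was -2.48 and -0.32. Genes chosen by 1 comparison tend to look smaller in the other, so the choice was reversed after the data were seen. The 674 genes higher by 2 or more in the resistant line had medians of 3.14 there and 3.02 with vorinostat, and the 375 lower by as much had -2.87 and 0.08. Over all genes tested the SD of the log2 fold change was 1.69 with vorinostat and 1.22 in the resistant line. Of tested genes under 1 CPM in untreated cells, 408 were higher and reached 1 CPM in the resistant line, and 298 did so in both.

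The 2 comparisons share the untreated libraries, so the overlap was set against simulations. Unchanged groups gave at most 2 genes higher in both, which shows only that shared controls alone make few calls. In 40 simulations added after the data were seen, the resistant changes were moved to other genes of the same untreated level, and at most 1025 genes were higher in both and 1042 lower in both, against 1524 and 1394 observed. Opposite directions came up for 1292 to 1425 genes there, against 1472, but those simulations gave fewer calls in the resistant line, with medians of 2640 higher and 2698 lower. Independent lists of the observed sizes would share 1052 higher and 1001 lower genes and hold 2057 in opposite directions. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.3665, against 0.1982 to 0.2439 with moved changes and a median of 0.502 with unchanged groups, where only the shared controls correlate. The covariance was 0.758, against at most 0.5054 with moved changes and a median of 0.0378 with unchanged groups. With the controls split after the data were seen, vorinostat against untreated library 1 and resistant against library 2 gave 1541 genes higher in both, 1377 lower in both and 1605 opposite, where independent lists of those sizes would hold 1084, 1033 and 2125. The other split gave 1586, 1481 and 2065, against 1293, 1164 and 2454. Pearson's r across genes was 0.325 and 0.293 with split controls, and 0.454 and 0.475 with both comparisons against library 1 or library 2 alone. Genes lower in both numbered 902 under upper-quartile scaling and 881 without resistant library 1, and genes in opposite directions numbered 979, 819 and 879 without vorinostat library 1, resistant library 1 and resistant library 2.

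**Figure D3:**
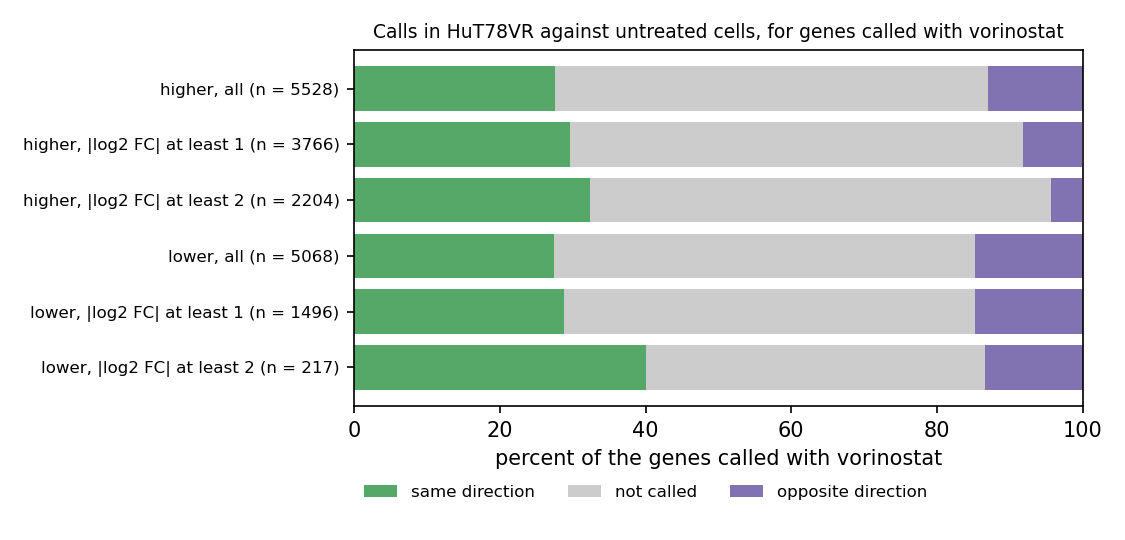
Percent of the genes called with vorinostat that were called in the same direction, not called or called in the opposite direction in the resistant line, by direction and by size of the vorinostat change (log2 of 0, 1 and 2 or more). Among genes that rose by 2 or more, 32.4% were called in the same direction and 4.26% in the opposite one.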

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

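Tests of neighbouring genes, of DNA dosage, of regions as the only source, of scaling for each class of opposite genes, of a response scaled down alike, of unrelated changes by simulation and of genes chosen by the resistant line were chosen after the results were seen. The regional shift itself was first noticed in an exploratory scan, and chromosome 15 was picked because it stood out. The test of scaling for the size of the response was written after the medians under TMM and the counts under other scalings were known, but before the medians under other scalings were computed.

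Opposite directions were called for 1472 genes, 723 higher with vorinostat and lower in the resistant line, such as HDAC11 (2.37 and -1.15), and 749 the other way, such as CFLAR (-1.38 and 1.22). They were picked out as differing between groups, but that resistant and vorinostat-treated cells differed in each of the 1472 follows from the opposite calls and adds no support, and simulations of unrelated changes, with fewer calls, gave 1292 to 1425. The lowest total under 3 other scalings was 102.7% of that under TMM, but this decides nothing, since scaling adds to 1 class what it takes from the other. Of the genes that fell with vorinostat, as few as 54.6% were still called (409 of 749 by library size alone). Of the genes that rose, at least 91.6% were still called. But the 3 scalings moved the vorinostat fold changes up, by a median of 0.004 to 0.324, so these genes could hardly lose the call. No scaling that lowers those fold changes was tried, so scaling stays open for both classes. Shifted regions held 32.5% of the opposite genes used, against 25.3% of all genes placed and 36.0% of those called in the resistant line, so the regions called were not the only source. Runs shorter than the window of 41 genes, or with medians under the threshold of 0.365, could be missed. A regional shift therefore stays open for opposite genes outside the regions called. The first test of regions used the ratio to all genes placed, 1.28, and was left undecided before the share inside the regions was examined. Each opposite gene is by definition called in the resistant line, and beside the 36.0% of genes called there 32.5% is no excess. The ratio therefore shows no enrichment particular to opposite genes, and whether regions add to the pattern stays open. A difference between an acute response and a selected line is a candidate explanation that was not tested apart from these.

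Whole regions were shifted in the resistant line, with chromosome 15 as the tested case. After a GC trend was removed 93.4% of its shift was kept, which argues against GC content as the whole cause, and 91.9% of its genes lay below the median of all genes, which argues against a few strongly changed neighbours. Its lower quartile lay -0.58 and its upper quartile -0.66 from those of the other autosomes, as a lower DNA dosage in the resistant line would give, so a change in chromosome number is a candidate explanation. DNA was not measured, and the test was made on the data that raised the idea. The GC step took 25 regions to 14 and 507 higher and 822 lower windows to 197 and 983: chromosome 11 from 111.9 to 134.3 Mb kept -0.63 of -0.67, but the region of chromosome 6 that holds the MHC class II genes no longer passed, and for such regions GC content stays open. The test of a few strongly changed neighbours was made for chromosome 15 only, so for the chromosome 6 region that explanation stays open too.

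Genes that changed by 2 or more with vorinostat changed less in the resistant line, at most 25.5% of the vorinostat median over 3 scalings and both directions. The pattern thus held under each of these scalings. But they moved vorinostat fold changes by a median of only 0.004 to 0.324 and resistant ones by -0.043 to 0.041. Beside medians of 3.33 and -2.48 with vorinostat, such moves could hardly have changed the outcome, so the test decides nothing about other scalings. Choosing genes by vorinostat favours the pattern: chosen by the resistant line, genes higher by 2 or more had 96.2% of its median with vorinostat and lower ones -2.6%, so the choice of genes stays open as the source for lowered genes. A single response scaled down alike for every gene was first judged by the share of these genes with the same sign in both, 69% for those that rose and 68.2% for those that fell, which decided nothing under the bounds first set. That criterion was then replaced, with both values already seen, by the share of genes called in the resistant line that were called in the opposite direction with vorinostat, 23.6%, which argues against such scaling as the whole account. With glmTreat 248 genes were opposite, beside 1265 higher and 1124 lower in the resistant line. That share is lower and falls short of the bound, so the verdict holds for the main test only. Whether drug was present in the wells of the resistant cells is not told by the labels and was decided by no value here, so loss of response and absence of drug stay open. Dose and length of exposure also differed between the groups, and their part was not tested.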

How the results depend on the processing

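All alternatives were planned except removal of mitochondrial rRNA and tRNA genes and a split of the untreated libraries between the comparisons, added after the data were seen, which moved no count by over 1.5 times. Of the genes called under TMM, 0 were called in the other direction under the alternatives compared gene by gene, and the share kept ranged from 38.3% (glmTreat, resistant against untreated) to 99.8%. The cause of the changes below was not tested, except that glmTreat and an adjusted p under 0.01 ask for more by construction and fits without a library hold fewer. Upper-quartile factors gave 902 genes lower in both comparisons, and library size alone gave 3113 lower with vorinostat and 3096 higher in resistant than in vorinostat-treated cells. With glmTreat the counts were 2701 lower with vorinostat, 1265 higher and 1124 lower in the resistant line, 3013 higher in resistant than in treated cells, 807 higher in both, 275 lower in both and 248 opposite. Under an adjusted p of 0.01 they were 1930 higher and 2097 lower in the resistant line, 968 higher in both, 823 lower in both and 737 opposite. Leaving out each library in turn gave 1959 to 3872 higher and 2035 to 3516 lower in the resistant line, 881 to 1608 lower in both and 819 to 1626 opposite, the lowest each time without resistant library 1. A lone library was assumed to vary like the other groups.

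List counts of 14, 10 and 9 (vorinostat and resistant against untreated, resistant against vorinostat) became 0, 0 and 0 with an estimated correlation in camera and 33, 32 and 39 by fry. The estimated correlation was 0.639 for DNA replication genes. But it lay near or below the preset 0.01 for ribosome (0.014), MHC class II (0.003) and neuronal genes (-0.034), whose calls were lost too. With few residual degrees of freedom that setting had little power, so the lost calls do not measure correlation among members. Each of the camera calls was kept by fry, by the block and by RLE and library-size scaling. Of 862 values of named genes 833 were called, and 139 of these lost the call in some alternative checked. That check left out glmTreat, an adjusted p under 0.01, the alternatives added after the data were seen and genes dropped by a filter. Reversals, counted where either value was called, numbered 11, all under library size alone: with vorinostat HDAC2 (0.28), MYC (0.042), ICOS (0.013), HLA-DRA (0.014), CD74 (0.053) and HEXA (0.037), and in resistant against vorinostat-treated cells HDAC1 (-0.22), PMAIP1 (-0.087), HSPA5 (-0.056), PDIA4 (-0.114) and IER3 (-0.015). Library codes run in a series that could pair the replicates, but deviations of paired replicates correlated across genes by only -0.10, 0.16 and -0.02. In a simulation added after the data were seen, with changes of 1 planted in 100 genes per level in the resistant line, 5 were recovered under 1 CPM in untreated cells, 57 at 1 to 10, 97 at 10 to 100 and 100 above, so at this depth changes of that size were mostly missed in genes under 1 CPM.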

Other observations

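Genes of apoptosis moved both ways. With vorinostat BMF (3.15), BNIP3L (1.73) and BBC3 (2.09) rose and BID fell by 1.49. Of 13 pro-apoptotic BCL2 family genes, 6 rose and 2 fell with vorinostat (10 and 2 by library size alone), and 4 were higher and 2 lower in the resistant line (camera adjusted p = 0.33 and 0.7). Of 12 survival factors, 3 rose and 6 fell with vorinostat, among them BCL2L1 (-1.84), and 2 were higher and 4 lower in the resistant line (adjusted p = 0.37 and 0.66). Of 16 death receptor genes, 6 rose and 4 fell, and 3 were higher and 6 lower in the resistant line, FAS being lower in both (-1.67 and -1.202). Of 23 p53 targets 10 were higher and 5 lower in each comparison with untreated cells, though library size alone gave 17 and 2 with vorinostat, and 8 were higher and 11 lower in resistant than in vorinostat-treated cells, or 2 and 14 by library size alone. Of 6 CDK inhibitors 3 were higher in each comparison with untreated cells, with 0 lower with vorinostat and 1 in the resistant line. None of these lists passed the camera threshold in any comparison.

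Genes that mark T cell subsets, cytokine signalling and other cell types also moved both ways. The chromatin organizer gene SATB1 was higher with vorinostat (3.32) and in the resistant line (4.33), and IL6R was higher in both (5.64 and 4.72). Counts of higher and lower members with vorinostat, then in the resistant line, were 11 and 10, then 4 and 10, of 27 T helper 2 and CTCL-associated genes. They were 8 and 7, then 3 and 7, of 18 cytotoxic genes, and 7 and 4, then 2 and 5, of 15 immune checkpoints. They were 23 and 10, then 13 and 10, of 46 chemokine and cytokine genes, and 10 and 11, then 4 and 13, of 23 JAK-STAT genes, where library size alone turned the first to 12 and 9 and upper-quartile scaling to 11 and 10. For 25 PI3K-AKT-mTOR genes they were 5 and 14, then 7 and 6, and library size alone turned the first to 8 and 5. For 31 antioxidant genes they were 9 and 13, then 10 and 3, and library size alone turned the first to 14 and 7 and upper-quartile scaling to 13 and 8. For 19 MHC class I genes they were 8 and 6, then 2 and 8, with B2M at -0.995 in the resistant line, on chromosome 15. Of 29 autophagy and lysosome genes 15 rose and 3 fell with vorinostat, and 7 were higher and 10 lower in the resistant line. For 24 glycolysis genes the counts were 8 and 12, then 7 and 3, for 24 cholesterol genes 2 and 4, then 1 and 7, where library size alone turned the first to 6 and 2 and upper-quartile scaling to 5 and 2, and for 3 glucuronidation genes 0 and 1, then 0 and 2. They were 5 and 4, then 1 and 4, of 11 B cell markers, 8 and 2, then 5 and 2, of 10 myeloid markers, 5 and 4, then 4 and 7, of 11 epithelial markers and 4 and 1, then 0 and 1, of 6 erythroid markers. They were 3 and 1, then 4 and 1, of 5 cancer-testis genes, 3 and 0, then 2 and 0, of 5 metallothioneins and 2 and 0, then 3 and 0, of 14 replication-dependent histones. Only 5 of 30 fixed cancer-testis genes, 5 of 11 metallothioneins and 3 of 18 glucuronidation genes were tested, and the filter favours members with reads in some group. None of these lists passed the camera threshold in any comparison. In the comparisons with untreated cells, against genes of the same untreated level and in a test added after the data were seen, more autophagy (6.9 at that rate), MHC class I (2.6) and JAK-STAT genes (4.1) rose with vorinostat, fewer autophagy (12.8) and cholesterol genes (12.9) fell and fewer histones (7.3) rose. More JAK-STAT (5.9) and epithelial genes (2) were lower in the resistant line (exact adjusted p from 0.00096 to 0.038 for these 8).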
